A study of Chamelea gallina with 30 samples.

How the data were processed

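Transcript levels were measured in digestive glands of the striped venus clam Chamelea gallina with a custom single-colour oligonucleotide array, labelled with the dye Cy3. Per the labels' protocols, RNA was extracted from pools of 5 digestive glands with an RNeasy kit, then amplified and labelled with the Agilent low-input protocol. The labels give 6 groups, made of 2 sites and 3 months, with 5 pools in each, and 1 array was hybridised per pool, which made 30 arrays. The number of clams per pool follows the extraction label, since the design text gives clam totals that do not match 5 pools of 5 at each site and month.

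The deposited scanner tables hold the intensity of each spot. Per the file headers and the design text, the slides were scanned at 2 sensitivities and read with Feature Extraction 9.5.1.1, which subtracted the background, divided out a smooth spatial trend and set a flag for spots well above background. The deposited intensity values had not been scaled between arrays. Each array held 15555 features, of which 536 were controls and 15019 were probes of 60 bases. The probe names fall into 12064 transcripts. The names end in P, N, S or AS, and what these endings stand for is not given in the sources used here. The files describe each of the 15019 probes as unknown and pair none with a gene name. Of 25 keyword lists of genes that were fixed before the data were examined, 0 could be matched to a probe, so the gene list tests were not run, and probes are given here by name and sequence. A second deposited table holds log2 values of the same arrays. It has values for 11620 of the probes and null for the others. How the authors scaled it is not given in the sources used here. Set against the scanner values of the same array, each of its columns correlated at r = 0.996 or more across probes with log2 brightness, and its column medians lay between 8.38 and 8.45. Its values therefore have a known scale and direction, while its exact centring stayed unknown. It was used only as an alternative. The 0/1 flags of the scanner tables were used as deposited.

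The main values were log2 of the processed intensity minus the array's own 75th percentile of it. A level of 0 is thus the brightness that 75% of probes do not exceed. Control spots were left out. Each probe name had 1 spot per array, so outlier-marked spots were kept, and saturated spots were kept as well. At most 5 probes were saturated and at most 22 were marked as outliers on any array. A probe was tested when it was well above background on at least 5 of the 30 arrays, and 11751 probes passed. Of the 15019 probes, 2754 shared their sequence with another probe, so counts of probes exceed counts of sequences. For arrays there is no read depth, and the number of arrays limits the precision.

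All 30 arrays entered 1 linear model with 6 group means, fitted with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom. Empirical Bayes moderation gave standard errors and p-values, which were adjusted with the Benjamini-Hochberg method over the 11751 probes in each comparison. A probe with an adjusted p under 0.05 is called here. The 7 comparisons of 2 groups were T4 with T7 in each month, August with July at each site and September with August at each site. A moderated F-test asked whether the difference between the sites changed over the months. Numbers of detected probes were compared with two-sided exact permutation tests. Since the labels give the pools only as separate samples of a site and month, the p-values measure the spread between pools. Ranges of fold changes are 95% confidence intervals from the same model. Where a probe was not well above background in any pool of the dimmer group, the fold is given as a lower bound. The bound sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. The bound holds for the background subtraction of the deposited intensity values and not under another. It makes no allowance for the spread between pools, so the 95% interval of the fitted fold can start below it. This was so for Chamelea_c30600_P, Chamelea_rep_c2459_AS (interval 4.26 to 30.4), Chamelea_rep_c12307_S and Chamelea_rep_c31667_P.

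The named probes were chosen by a rule written before the data were examined. In each comparison these are the 2 called probes with the largest rise and the 2 with the largest fall, among those well above background in every pool of the brighter group and with no overlap between the 5 pools of each group. One probe was taken per transcript and per sequence. Where 2 probes of a transcript were tested, the text says where they disagree.

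The arrays lay on 4 slides that were scanned in 2 sessions, slides 1 and 2 in the first and slides 3 and 4 in the second. Every slide held more than 1 group, so each comparison was also fitted with slide as a fixed term and with slide as a random block, and the sign of each called probe was read within each slide that held both groups. This reading is not separate evidence, since a probe whose pools do not overlap must keep its sign, which holds for 159 of the 226 calls between the beds in August. The T4 arrays of September lay on slides 1 and 2 and those of August on slides 3 and 4, so this comparison has no slide in common and its slide term rests on the other groups. The fit was tested on simulated data made from the means and spreads of the 11751 probes, with 200 probes changed between T4 and T7 in August. Over 10 such simulations, 44.0% of the probes changed 2-fold and 76.3% of those changed 4-fold were found, and 6.30% of the calls were false. The simulated noise was normal and independent between probes and arrays, with no slide effects or outlying pools. These shares need not hold for the real calls.

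Alternatives planned beforehand were normexp background correction with an offset of 50, quantile normalization, the median in place of the 75th percentile, the deposited log2 table, no filter, a filter that asks for all 30 arrays, averaging of the probes of a transcript, a fit of only the 2 groups compared, a replicate block, slide as a block, array weights, a trended and robust spread, 2 stricter thresholds, and leaving out each pool in turn. Added after the data were seen were leaving out outlier-marked spots, slide as a fixed term for the named probes, averaging of identical sequences, a slide adjustment made before the fit, a correction for GC content and leaving out 2 pairs of pools. Figures were drawn with matplotlib 3.10.9.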

Results

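Transcript levels were compared between 2 beds of the striped venus clam Chamelea gallina, a burrowing bivalve of sandy bottoms that is dredged for food. Clams of 25 mm came from sites T4 and T7 on the Abruzzo coast of Italy, 0.4 km from the shore, in July, August and September 2014. Fishing cooperatives had reported a collapse of the harvest at T4 in the spring before. The digestive gland, the organ of digestion and nutrient storage in bivalves, was dissected, and 5 pools of 5 glands were measured per site and month. The series asks how clams of 2 beds with different mortality differed in gene expression. The files name no genes, so transcripts are given by probe name and 60-base sequence.

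On the 30 arrays, between 9584 and 11457 of 15019 probes (63.8% to 76.3%) were well above background. The number was 11096 ± 235 (SD, n = 5) at T4 in July, 10725 ± 305 (n = 5) in August and 10253 ± 327 (n = 5) in September. At T7 it was 10901 ± 390 (SD, n = 5), 10433 ± 315 (n = 5) and 10235 ± 399 (n = 5). None of the 7 differences between neighbouring groups passed an exact permutation test after adjustment (lowest raw p = 0.0556, adjusted p = 0.241, for September against August at T4). The numbers of July and September were not tested against each other. The 75th percentile of brightness ranged from 595 to 1395 between arrays. Any pair of arrays correlated across probes at r = 0.886 to 0.961. The first principal component held 17.9% of the variance. Month accounted for 61.9% of it, site for 8.70% and slide for 18.5%. Spots of identical sequence on an array differed by a median SD of 0.07 log2, against a median SD of 0.46 log2 between pools of a group.

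**Figure D1:**
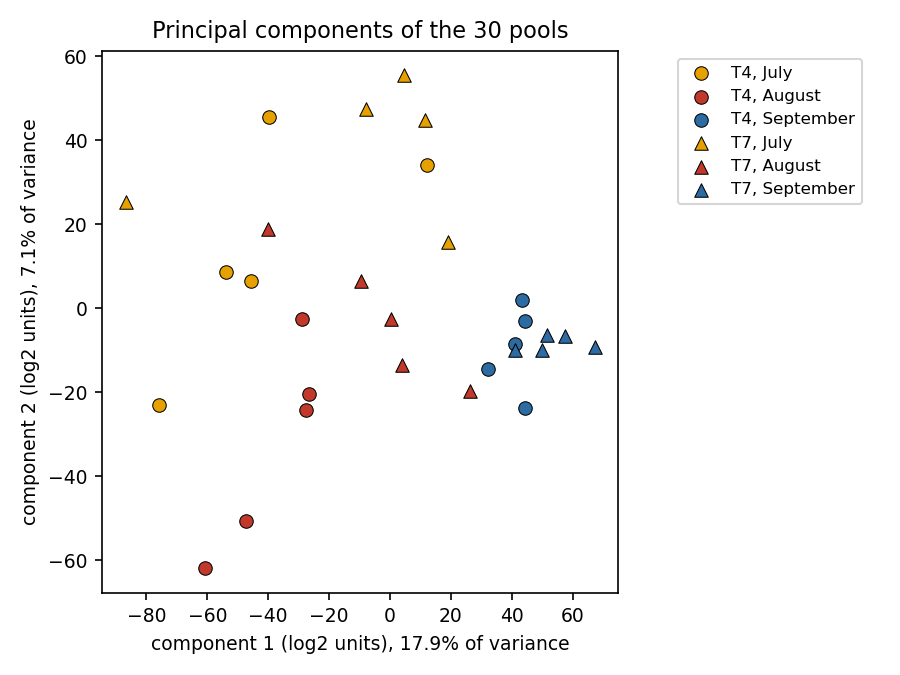
Each point is 1 of the 30 pools placed on the first 2 principal components of the 11751 tested probes, in log2 units, with circles for T4, triangles for T7 and a colour for each month. The 10 September pools of both sites lie together at the right, from 32.2 to 67.2 on component 1, while the July and August pools spread from -86.7 to 26.2.

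**Figure D2:**
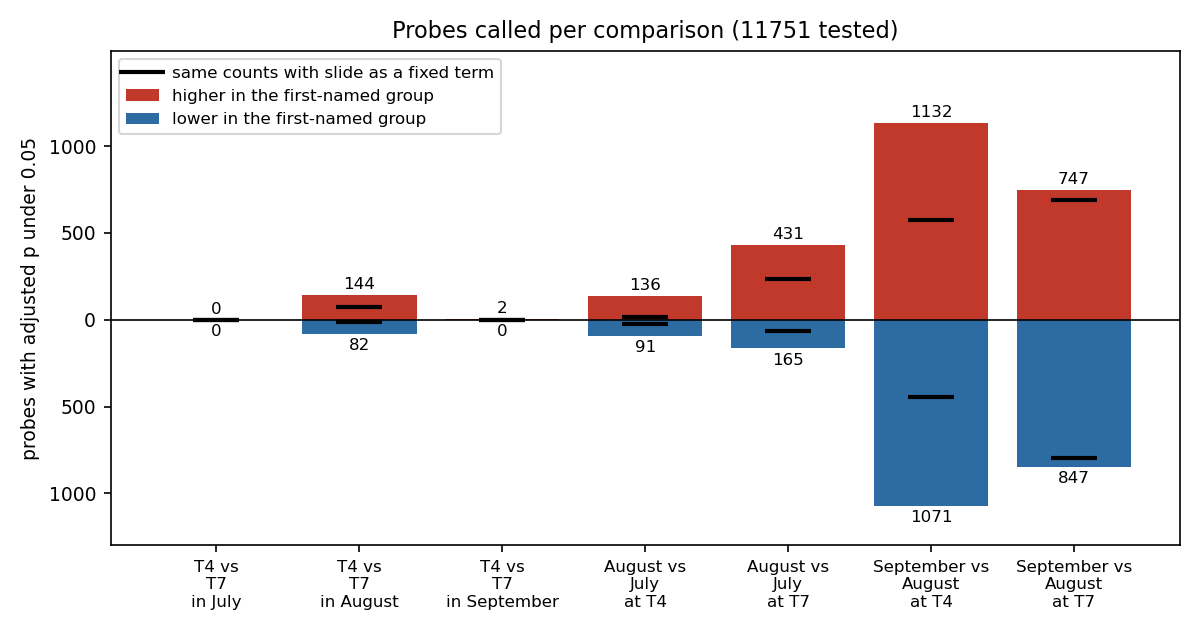
Bars give the number of probes with adjusted p under 0.05 in each of the 7 comparisons, above 0 for probes higher in the first-named group and below 0 for probes lower in it, and black ticks give the same counts with slide as a fixed term. September against August has the tallest bars, with 1132 higher and 1071 lower at T4, and T4 against T7 in July has 0.

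The first question was whether the clams of T4 and T7 differed within a month. In July, limma called 0 of 11751 probes (lowest adjusted p = 0.0697). At an unadjusted p under 0.05 there were 740 probes, where chance alone gives 588. The 5 pools of T4 and the 5 of T7 did not overlap for 123 probes, where chance gives 0.794% of probes, or 93.3. The count was also 0 with slide as a fixed term and with slide as a random block. Pools of July did not all lie nearest to their own group. Over all tested probes, T4 pool 4 correlated at r = 0.965 with the T7 mean and at 0.954 with the other T4 pools. T7 pool 2 correlated at 0.954 with the T4 mean and at 0.928 with the other T7 pools.

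In August, 144 probes were higher and 82 lower at T4 than at T7, though the excess depended on the processing. By the bound used here, Chamelea_c30600_P was at least 19.0-fold higher at T4, and the 95% interval of its fitted fold was 12.8 to 160. Its level was -1.57 ± 1.64 log2 (SD, n = 5) there and -7.07 ± 0.77 (n = 5) at T7, where it was not well above background in any pool (limma adjusted p = 0.000933). Its sequence is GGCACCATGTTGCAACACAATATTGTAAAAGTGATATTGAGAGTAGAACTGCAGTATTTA. Chamelea2_rep_c1707_S (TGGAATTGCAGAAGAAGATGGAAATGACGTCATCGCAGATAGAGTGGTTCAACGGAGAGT) was 47.5-fold higher at T4, with a wide 95% interval of 6.56 to 345 (limma adjusted p = 0.0326). It was well above background in 5 pools of T4 and 3 of T7, and its call was lost without any of 7 of the 10 pools. The difference of 5.57 log2 was 4.79 without T7 August pool 2, 6.25 without pool 1, 6.21 without pool 3, 6.97 in the deposited log2 table and 7.43 ± 1.60 (SE) with slide as a fixed term. The other probe of its transcript, named AS, differed by 1.98 log2 and was not called (adjusted p = 0.103). Chamelea_rep_c13630_N (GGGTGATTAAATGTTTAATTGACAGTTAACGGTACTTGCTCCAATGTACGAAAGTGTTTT) was 13.1-fold lower at T4, with -4.33 ± 1.39 log2 (SD, n = 5) against -0.61 ± 1.01 (n = 5) at T7. Its limma adjusted p of 0.00869 became 0.0681 with slide as a fixed term, where the difference was -3.78 ± 0.96 log2 (SE) against -3.72 ± 0.77, within a range of 0.00131 to 0.0681 over 18 alternatives. Chamelea_c31445_AS (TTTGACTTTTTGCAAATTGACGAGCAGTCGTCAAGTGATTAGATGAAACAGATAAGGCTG) was 6.35-fold lower at T4 (95% interval 2.72 to 14.8, limma adjusted p = 0.0158). The S probe of the same transcript differed by -0.70 log2 and was not called (adjusted p = 0.373). With normexp background correction, Chamelea2_rep_c1707_S and Chamelea_c31445_AS were no longer called (3.35 and -1.23 log2, adjusted p = 0.0562 and 0.13). Chamelea_c30600_P differed by 2.12 log2 there, less than its lower bound above, and Chamelea_rep_c13630_N by -2.43. Without T4 August pool 3 the fitted difference of Chamelea_c30600_P was 6.14 log2 against 5.50, and it was 6.22 in the deposited table and 6.38 ± 1.02 (SE) with slide. Over the 18 alternatives the limma adjusted p ranged from 0.000761 to 0.102 for Chamelea2_rep_c1707_S and from 0.000336 to 0.13 for Chamelea_c31445_AS. For Chamelea_c30600_P it ranged from 2.77e-05 to 0.0115.

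The 226 August calls stood for 210 sequences, and their median difference was 2.51-fold. Of the probes called with at least a 2-fold difference, 136 were higher and 20 lower at T4. Among the dimmest 2938 of the tested probes 42 were called higher and 3 lower at T4, and among the brightest 2938, 24 were called higher and 40 lower. The split was near even, with 108 higher and 100 lower, among probes well above background on all 30 arrays, and with 347 higher and 344 lower in the deposited log2 table. With slide as a fixed term, limma called 87 probes, 72 of them higher at T4. The 149 calls that ended had a median difference of 1.11 log2 before and 1.03 after, and a median SE of 0.26 before and 0.31 after. On slide 3, with 4 arrays of T4 and 1 of T7, 225 of the 226 probes kept their sign, and so did 225 on slide 4, with 1 array of each. Fitted on the 10 August arrays alone, 45 probes were called, 38 of them higher.

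In September, limma called 2 probes, both higher at T4, and 729 had an unadjusted p under 0.05. Chamelea_c9393_N (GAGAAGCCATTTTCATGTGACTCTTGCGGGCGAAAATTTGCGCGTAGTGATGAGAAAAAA) was 4.60-fold higher at T4 (95% interval 2.68 to 7.90, limma adjusted p = 0.0238). Its level was 2.98 ± 0.63 log2 (SD, n = 5) at T4 and 0.77 ± 0.23 (n = 5) at T7. The second, Chamelea_c35855_N (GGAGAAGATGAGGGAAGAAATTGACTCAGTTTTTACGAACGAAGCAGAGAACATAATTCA), fell outside the rule for named probes and was chosen after its values were seen. It was well above background in 3 pools of T4 and none of T7, at least 1.43-fold higher (adjusted p = 0.0177), with 0.74 log2 under normexp (adjusted p = 0.651). Both calls were lost with slide as a fixed term (adjusted p = 0.0726 for each) and with the replicate block. With slide the differences were 2.19 ± 0.41 log2 (SE) against 2.20 ± 0.38, and 2.63 ± 0.47 against 2.68 ± 0.43, and with the block they were identical to those reported. Over 18 alternatives their adjusted p ranged from 0.00391 to 0.164 and from 6.25e-05 to 0.651. Within slides 1 and 2, the 2 that held both groups, both probes were higher at T4, as they must be since their pools did not overlap. Leaving out a pool ended the call of Chamelea_c9393_N in 8 of 10 cases and that of Chamelea_c35855_N in 5.

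The second question was how levels changed from July to August at each bed. At T4, 136 probes rose and 91 fell. Chamelea_rep_c3702_P (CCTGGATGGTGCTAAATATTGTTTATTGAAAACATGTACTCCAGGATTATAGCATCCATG) fell 12.3-fold (95% interval 6.16 to 24.7, limma adjusted p = 0.000415), from 1.11 ± 1.24 log2 (SD, n = 5) to -2.51 ± 0.66 (n = 5). At T7 the same probe differed by -0.89 log2 and was not called (adjusted p = 0.308), and a difference between the sites was not shown by the interaction test (adjusted p = 0.294). Chamelea2_rep_c2096_P (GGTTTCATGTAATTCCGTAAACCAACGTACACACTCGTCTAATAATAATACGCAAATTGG) fell 5.35-fold (limma adjusted p = 0.0192), and a second probe with this sequence differed by -2.38 log2. With normexp Chamelea2_rep_c2096_P differed by -1.82 log2. Chamelea_rep_c11257_AS (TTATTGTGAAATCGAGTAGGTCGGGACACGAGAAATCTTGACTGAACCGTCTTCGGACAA) rose 25.5-fold (95% interval 6.40 to 102, limma adjusted p = 0.0167). Its level in August was 3.09 ± 2.75 log2 (SD, n = 5) and in July -1.58 ± 1.47 (n = 5). T4 August pool 4 stood at 7.55 log2 and the other 4 pools of August at 3.38 or less, and the difference of 4.67 log2 was 3.56 without that pool, 5.32 without T4 August pool 1 and 4.03 without T4 July pool 4. Chamelea2_rep_c738_S (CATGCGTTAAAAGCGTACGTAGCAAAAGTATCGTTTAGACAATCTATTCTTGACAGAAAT) rose by 4.04 log2 (limma adjusted p = 0.0238), from 1 pool well above background in July to 5 in August. With normexp the difference was 1.31 log2, and it was 2.67 in the deposited table, so its size is uncertain, and the call was lost without any of 4 of the 10 pools. The AS probe of its transcript differed by 0.28 log2 and was not called, and a second probe of the same sequence differed by 3.75 log2. With slide as a fixed term, only Chamelea_rep_c3702_P among these 4 was still called (-4.25 ± 0.60 log2, SE, against -3.62 ± 0.49, adjusted p = 0.00184), and Chamelea_rep_c11257_AS, Chamelea2_rep_c738_S and Chamelea2_rep_c2096_P had adjusted p = 0.112, 0.25 and 0.0867. Their differences with slide were 4.58 ± 1.27 log2 (SE) against 4.67 ± 0.97, 2.65 ± 1.02 against 4.04 ± 0.93, and -2.62 ± 0.68 against -2.42 ± 0.53. These adjusted p were the highest over 18 alternatives, and the lowest were 0.00175, 0.0192 and 0.00127, while Chamelea_rep_c3702_P ranged from 2.69e-06 to 0.00328.

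The 227 calls at T4 had a median difference of 1.73-fold, and 78 were at least 2-fold. The count fell to 44 with slide as a fixed term, with 18 up and 26 down. The 191 calls that ended had a median difference of 0.77 log2 before and 0.80 after, and a median SE of 0.18 before and 0.23 after. It was 6 when the 10 arrays were fitted alone. Slide 4 was the only one with arrays of both months, 1 of August and 3 of July, and there 227 of 227 probes kept their sign. The normexp correction moved the count to 374, with 274 up.

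At T7, 431 probes rose and 165 fell from July to August. Chamelea_rep_c3907_N (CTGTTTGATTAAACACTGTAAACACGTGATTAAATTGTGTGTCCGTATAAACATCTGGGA), a bright probe, rose 9.16-fold (95% interval 3.18 to 26.4, limma adjusted p = 0.0156), from 1.84 ± 1.80 log2 (SD, n = 5) to 5.03 ± 0.31 (n = 5). Chamelea_rep_c2459_AS (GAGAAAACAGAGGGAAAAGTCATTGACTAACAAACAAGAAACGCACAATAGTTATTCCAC) rose at least 6.94-fold by the bound used here, from no pool well above background to 5 (limma adjusted p = 0.00494). Chamelea_c31874_N (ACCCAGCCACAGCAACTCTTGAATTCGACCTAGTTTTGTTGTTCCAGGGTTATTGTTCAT) fell by 3.92 log2 (limma adjusted p = 0.00371), and was well above background in 1 pool of August. Chamelea2_rep_c1465_N (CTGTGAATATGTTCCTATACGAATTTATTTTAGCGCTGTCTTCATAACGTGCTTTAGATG) fell by 3.64 log2 (limma adjusted p = 0.0274), with a difference of -1.91 under normexp and -2.95 without T7 August pool 4, so its size is uncertain too. A second probe of this sequence differed by -3.79 log2 and was not called (adjusted p = 0.0574). The call of Chamelea2_rep_c1465_N was lost without any of 4 of the 10 pools and with slide as a fixed term (adjusted p = 0.0707), where its difference was -3.82 ± 1.15 log2 (SE) against -3.64 ± 0.95. With normexp, Chamelea_rep_c2459_AS and Chamelea_c31874_N were no longer called and differed by 1.28 and -0.87 log2 (adjusted p = 0.0708 and 0.126), so the sizes of both changes are uncertain and the former lies under its bound. Over 18 alternatives the adjusted p of Chamelea2_rep_c1465_N ranged from 0.00622 to 0.0838, and those of the latter pair from 0.00118 to 0.0708 and from 0.000261 to 0.126.

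The 596 calls at T7 had a median difference of 1.63-fold, and 173 were at least 2-fold, 94 up and 79 down. Under quantile normalization 283 rose and 214 fell, so the excess of rises depended on the scaling. Of the 100 brightest probes, 12 rose and 0 fell. With slide as a fixed term the count was 303, with 236 up. The 344 calls that ended had a median difference of 0.63 log2 before and 0.60 after. Within slides 3 and 4, each with 1 array of either month, 586 and 590 of the 596 probes kept their sign. Fitted on the 10 arrays alone, the count was 47. Between the beds, 61 probes were called up and 29 called down at both, none in opposite directions, where independent lists would share 4.99 and 1.28. These comparisons share no array. Across probes, which are not independent replicates, the changes correlated at r = 0.278, and 4 of 100 splits of the T7 pools gave as high a value.

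The third question was how levels changed from August to September. At T4, 1132 probes rose and 1071 fell. The probe Chamelea_rep_c3702_P, which had fallen in August, rose 50.2-fold (95% interval 25.1 to 101, limma adjusted p = 7.93e-08), to 3.14 ± 0.48 log2 (SD, n = 5). Chamelea_rep_c758_S (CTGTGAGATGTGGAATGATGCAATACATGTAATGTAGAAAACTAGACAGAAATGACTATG) rose 14.2-fold (95% interval 6.13 to 32.8, limma adjusted p = 6.59e-05), or by 3.83 log2 against 2.16 with normexp. Chamelea_rep_c12307_S (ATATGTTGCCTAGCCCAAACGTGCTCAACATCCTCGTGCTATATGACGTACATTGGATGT) fell at least 169-fold, from 1.37 ± 2.72 log2 (SD, n = 5) to a level not well above background in any pool (limma adjusted p = 0.000981). Chamelea_rep_c11427_S (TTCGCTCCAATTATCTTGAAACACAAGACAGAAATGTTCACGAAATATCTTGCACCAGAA) fell by 7.74 log2 (limma adjusted p = 5.23e-05), and 1 pool of September was still well above background. With normexp Chamelea_rep_c12307_S differed by -5.30 log2, less than its lower bound above, and Chamelea_rep_c11427_S by -4.63, so the sizes of both falls are uncertain. The 95% interval of the fitted fold of Chamelea_rep_c12307_S was 34.6 to 5128, so it starts below the bound. Its fitted difference was -8.72 log2, with -8.07 without T4 August pool 1, -9.85 without pool 5, -9.59 in the deposited table and -10.43 ± 2.33 (SE) with slide as a fixed term. That of Chamelea_rep_c3702_P was 5.65 log2, and 6.33 ± 0.63 (SE) with slide. These 4 probes were also called with slide as a fixed term and without any single pool.

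Large falls outnumbered large rises at T4. Of the called probes, 208 fell and 39 rose at least 4-fold, while the median difference over all 2203 was 1.83-fold. Among the called probes there were 224 falls and 58 rises in the dimmest 2938, against 290 and 506 in the brightest 2938. The groups did not overlap for 1522 probes, where chance gives 93.3. With slide as a fixed term the count was 1021 (575 up and 446 down), and 953 of the 2203 probes were called again. The other 1250 kept their sign, with a median difference of 0.82 log2 before and 0.70 after and a median SE of 0.23 before and 0.30 after. No slide held T4 arrays of both months, so within-slide values could not be had. Centring on the median in place of the 75th percentile gave 1642 rises and 716 falls.

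At T7, 747 probes rose and 847 fell. Chamelea_rep_c758_S rose here too (limma adjusted p = 1.18e-05), from 3 pools well above background in August to 5 in September and from -5.52 ± 1.11 log2 (SD, n = 5) to -0.26 ± 0.71 (n = 5), a difference of 5.26 log2 that was 3.06 with normexp, so its size is uncertain. Chamelea_rep_c3702_P rose by 4.17 log2 (limma adjusted p = 1.2e-05). Chamelea_c21245_P (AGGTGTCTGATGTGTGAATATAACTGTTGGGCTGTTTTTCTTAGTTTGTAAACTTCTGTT) rose by 5.31 ± 1.44 log2 (SE, limma adjusted p = 0.0145), by 1.89 log2 with normexp and by 6.07 log2 without T7 August pool 2, so its size is uncertain. It was well above background in 1 pool of August and 5 of September. Chamelea_rep_c31667_P (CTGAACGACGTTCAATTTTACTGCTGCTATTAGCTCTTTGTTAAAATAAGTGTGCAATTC) fell at least 15.1-fold (limma adjusted p = 0.00224), to a level not well above background in any pool, and differed by -2.26 log2 with normexp, less than that bound. Chamelea_c20294_P (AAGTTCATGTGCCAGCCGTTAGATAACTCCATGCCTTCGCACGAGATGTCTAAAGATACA) fell by 5.22 log2 (limma adjusted p = 0.00115), and differed by -3.01 with normexp.

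**Figure D3:**
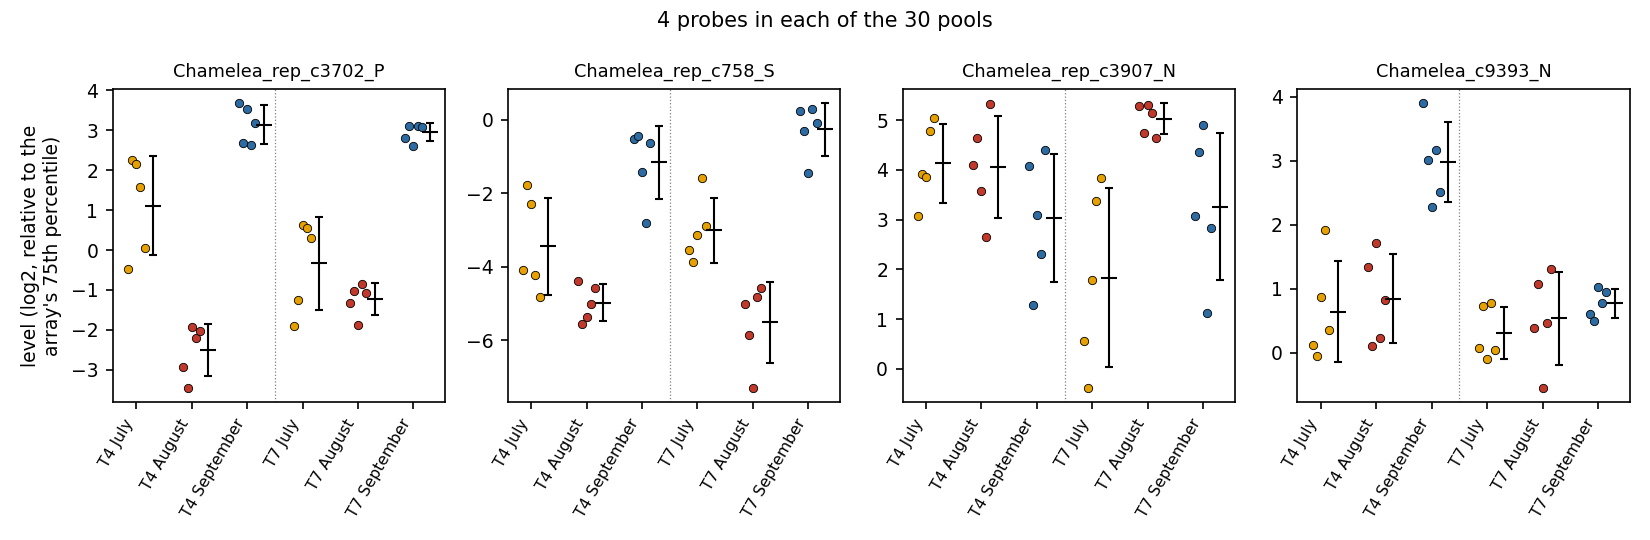
Each point is the level of a probe in 1 pool, in log2 relative to the array's 75th percentile, for 4 named probes in the 6 groups, and the bars give the mean and SD of the 5 pools. Chamelea_rep_c3702_P and Chamelea_rep_c758_S are highest in September at both sites, with means of 3.14 and 2.95 for the former at T4 and T7, and Chamelea_c9393_N stands at 2.98 at T4 in September against 0.77 at T7.

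The 1594 calls at T7 had a median difference of 1.71-fold, and 454 were at least 2-fold, 159 up and 295 down. The count was 1486 with slide as a fixed term. On slides 2, 3 and 4, which held both months, 1593, 1499 and 1566 of the 1594 probes kept their sign. The median probe fell by 0.15 log2 at T7 under the 75th percentile and by 0.00 under quantile normalization, so rises and falls here are relative to that shift. With quantile normalization 792 rose and 513 fell, with median centring 1180 rose and 340 fell, and after a correction for GC content 1000 rose and 560 fell, so that which direction was more frequent depended on the processing. Of the 100 brightest probes, 27 fell and 0 rose. Fitted on the 10 arrays alone, the count was 872.

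The change from August to September was shared between the beds. Of 11751 probes, 519 were called up and 362 called down at both, and 1 was called in opposite directions, where independent lists would share 72.0 and 77.2. Of the 2203 probes called at T4, 92.0% had the same sign at T7. These comparisons share no array, and across probes the changes correlated at r = 0.504 (rho = 0.532). With slide as a fixed term, 555 probes were called in the same direction at both beds.

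**Figure D4:**
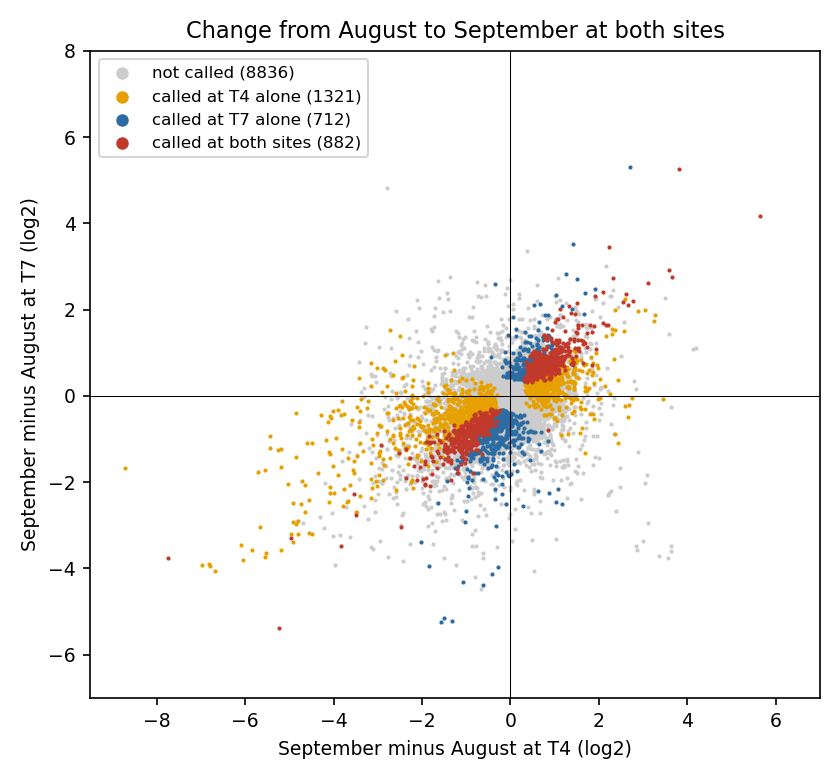
Each point is 1 of 11751 probes, with its September minus August difference (log2) at T4 on the horizontal axis and at T7 on the vertical axis, coloured by the site at which it was called. The 882 probes called at both beds lie along the diagonal, all but 1 in the same direction at both.

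The last question was whether the difference between the beds changed over the months. The F-test of the site by month interaction in limma called 0 of 11751 probes (lowest adjusted p = 0.0843), and 978 had an unadjusted p under 0.05, where chance gives 588. The count was 1 with slide as a fixed term and 0 with slide as a random block. A probe called in one month or at one bed and not in another is therefore not shown to differ between them. The differences between the beds in July and August, from separate arrays, correlated across probes at r = 0.286, those of August and September at 0.133, and those of July and September at 0.0389. Of the 226 probes called in August, 84.1% had the same sign in July and 76.1% in September.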

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

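The tests of slide and GC content in September, of the slide shifts in the deposited table, and of the slide effect in the scanner values were chosen only after the result was seen, and so was the slide adjustment before the fit. A pool is named below where its gap to the nearest of the 5 pools of its group exceeded Dixon's 95% limit. Of 73 such groups of values 10 held one, where chance gives about 3.65.

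For 4 pools the value that stood apart was the number of probes more than 1 log2 above every other array. It was 38 in T4 July pool 2 (next in the group 12), 156 in T4 August pool 4 (next 42), 87 in T7 July pool 2 (next 28) and 28 in T7 September pool 1 (next 8). The median correlation with the other pools of the group was 0.912 in T7 July pool 2, where the next was 0.941. In T4 September pool 2 it was 0.9528, above the next at 0.9483. Chamelea_c31445_AS stood at -3.011 log2 in T7 August pool 5 (next -2.32) and Chamelea_rep_c11257_AS at -4.136 in T4 July pool 4 (next -1.46). Chamelea2_rep_c738_S stood at -6.273 log2 in T4 July pool 4 (next -8.37), and Chamelea_c21245_P at -4.28 in T7 August pool 2 (next -7.88).

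In 100 of the 126 possible splits of the 10 pools of each comparison, the real one included, probes were called as in the report. No other split reached the real count for T4 against T7 in August (226, highest other 20) or in September (2, highest other 1), for August against July at T4 (227, highest other 83) and T7 (596, highest other 42), or for September against August at T4 (2203, highest other 482) and T7 (1594, highest other 293). Each real split was thus 1 of 100 with as many calls, and chance was excluded at that level except for T4 against T7 in September. There the result rests on 2 calls against 1, and 6 other splits gave a call, so chance is not excluded. For July and for the interaction the real count was 0, which all 100 splits or draws must reach, so this count says nothing about chance there. The highest other was 148 for July, which points to a structure among those pools, and 36 for the interaction.

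September differed from August at both beds. At T7, 1486 probes were called with slide as a fixed term against 1594 without it, which argues against slide or scan session as the whole cause there. A correction for GC content left 3790 calls over both beds against 3797, though at T7 it turned 747 rises and 847 falls into 1000 and 560, and only 1 of 100 splits of the T7 pools, the real one, correlated as highly with the T4 difference (0.504, highest other 0.448). At T4 the count with slide was 1021 against 2203; the 1250 probes that lost their call kept their sign, with a median difference of 0.70 log2 against 0.82 and standard errors 1.33 times as large, so the loss is mostly one of precision and does not show a slide effect, but with no slide in common the part of slide stays open for them. Season and any other change at the beds over these weeks may underlie the shared part, and were not tested.

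The deposited log2 table called more probes than the scanner values, such as 1303 against 227 for August against July at T4. Its slide shifts correlated at r = 0.998, over probes and slides, with those removed by a slide adjustment that protects the group means, against 0.685 without protection, but were 0.648 times as large, which suggests an adjustment of this kind and not this one exactly. Arrays of a slide did not deviate together from their group means in the scanner values (consensus correlation -0.0182), which argues against a slide effect common to most probes within groups. Groups were spread unevenly over slides, so a slide effect that coincides with groups would enter the group means. This value cannot speak to it. Adjusting beforehand gave the log2 differences of a fit with slide as a term but standard errors 0.813 times as large, and for August against July at T4 it gave 1179 calls against 57 with slide in the fit of the same quantile-normalized values. With shuffled groups, calls were summed over the 7 comparisons. Adjusted values then gave a median of 7 calls (95% interval 5 to 10) against 0 unadjusted. There was any call in 93 against 31 of 100 draws, with up to 1199 and 450 in a draw. This leaves open how many of the table's calls the adjustment made.

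T7 July pool 2 and T4 August pool 4 held 87 and 156 probes far above every other array. These showed no clear clustering on the array. For the pool with fewer, 31 of 100 random probe sets lay as close, short of the number set beforehand as evidence against a blemish. Of spots with the same sequence, at a median distance of about 75.6 spots, 92.9% were raised too, which argues against a blemish and against single aberrant spots. Their median GC content was within 0.83 percentage points of all tested probes. This describes the array's own probes and not the RNA that bound them. It therefore cannot tell whether RNA of a different base composition was present. The probes were counted against all 30 arrays, so no exchange of labels can make them, and no biological explanation was tested.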

How the results depend on the processing

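The slide adjustment before the fit, the GC correction, averaging of identical sequences, leaving out outlier-marked spots, slide as a fixed term for named probes, and leaving out the 2 pools that stand apart or the 2 July pools closer to the other bed were chosen after seeing the data. Of 167 counts under settings other than leaving out a pool, 119 stayed within 1.5 times the reported count and 48 did not. The cause was not tested except where named. For T4 against T7 in July the count was 3 with the deposited table, the replicate block and array weights each, and 103 without the 2 July pools, which were picked by how they lie. In August it was 691 with the deposited table, 45 with only the 10 arrays, 87 with slide as a fixed term, 81 at an adjusted p under 0.01, 596 adjusted for slide beforehand and 141 without the 2 pools that stand apart. In September it was 1 with normexp and with the filter on all 30 arrays, 11 with the deposited table, 7 adjusted beforehand, and 0 with only the 10 arrays, the replicate block, slide as a fixed term and an adjusted p under 0.01. August against July at T4 gave 374 with normexp, 145 with the median, 1303 with the deposited table, 365 with the all-array filter, 6 with only the 10 arrays, 44 with slide as a fixed term, 78 at 2-fold, 23 at 0.01, 1179 adjusted beforehand and 115 without the 2 pools. At T7 it gave 309 with the median, 1322 with the deposited table, 47 with only the 10 arrays, 303 with slide, 173 at 2-fold, 112 at 0.01, 1150 adjusted beforehand, 329 without the 2 pools and 366 without the 2 July pools. September against August at T4 gave 3316 with the deposited table, 1021 with slide, 900 at 2-fold and 1211 at 0.01. At T7 it gave 872 with only the 10 arrays, 454 at 2-fold and 719 at 0.01. The interaction gave 2 with quantile normalization, 73 with the deposited table, 1 with slide and 58 adjusted beforehand. A stricter threshold lowers a count by construction. Fewer arrays to estimate the spread can lower it too, though without T4 August pool 3 the count between the beds in August rose from 226 to 328.

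Leaving out each pool in turn gave 0 to 2 for July, 118 to 328 for August and 0 to 2 for September between the beds, 92 to 318 and 279 to 549 for August against July at T4 and T7, 1860 to 2120 and 1154 to 1592 for September against August, and 0 to 10 for the interaction. The August count moved by over 1.5 times without T4 August pools 2 (125), 4 (143) or 5 (139) or T7 August pools 3 (118) or 5 (127). August against July at T4 did so without T4 July pools 1 (121), 3 (92) or 5 (122) or T4 August pools 1 (139), 2 (123) or 4 (108), and at T7 without T7 July pool 2 (364) or T7 August pools 3 (279) or 4 (369). The September count fell to 0 without T4 pool 1 or T7 pools 2, 3, 4 or 5 and to 1 without T7 pool 1, and July rose to 1 without T4 pools 3 or 4 and to 2 without T7 pools 2 or 4. The interaction gave 10 without T4 August pool 3, 3 without T7 September pool 1, 2 without T7 July pool 4 or T7 August pool 2, and 1 without T4 July pools 1 or 2 or T4 September pool 5.

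The 22 log2 differences of 20 named probes kept their sign in all 176 values under other settings and all 220 without a pool, and lost the call in 14 and 29 of these. Without a pool the sign could not change, since the pools compared did not overlap for any named probe, so the 220 signs are no evidence. The calls lost without a pool fell on 6 of the 22. Replicate numbers did not pair the pools: deviations correlated at a mean of -0.0045 between pools of the same number and 0.00115 between others, and 5 of 30 pools were closest to their own number. Gene list tests were not run, since no probe has a gene name, keeping outlier-marked spots was already the choice for the reported values, and a fit of only the compared groups is the full fit for the interaction. Leaving out the 78 marked spots of tested probes moved no count by over 1.5 times. Signal over background limits dim probes: 3268 of 15019 were not tested, and normexp, whose offset draws dim levels together, gave smaller folds for named probes near background.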

Other observations

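The test of a swap partner in July, the tests of September against July, of the site difference in July and the fall at T7 in the set of transcripts below, and of the spread between pools were chosen only after the result was seen.

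Over all 3 months together, 111 probes were higher and 36 lower at T4 than at T7, and 0 probes separated the beds without overlap in every month. With the site labels shuffled within months, 1 of 100 draws, the real one, had as many calls (highest other 40), which excludes chance at that level. With slide as a fixed term 115 were called, 106 of them among the 147, and 104 of the 147 were also called in August alone.

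September also differed from July. At T4, 535 probes were higher and 545 lower in September (1080 in all, highest other split 7), and at T7 735 were higher and 640 lower (1375, highest other 107), so that in each case 1 of 100 splits, the real one, had as many calls. At both beds 329 were higher and 201 lower, none opposite, where independent lists would share 33.5 and 29.7. Such splits do not speak to slide or scan session, and no count with slide as a fixed term is given for September against July.

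The 192 sequences that fell at least 4-fold at T4 from August to September may form a set that varies together. Their deviations correlated at a median r of 0.105 over the 20 pools of the other groups, above the highest of 100 random sets (0.0390) yet below the 0.3 set beforehand, so this stays open. The set mean was -2.68 ± 0.79 log2 (SD, n = 5), -1.95 ± 0.34 (n = 5) and -5.30 ± 0.13 (n = 5) at T4 in July, August and September, and -3.99 ± 0.93, -4.02 ± 0.60 and -5.27 ± 0.24 at T7. It was 1.31 log2 higher at T4 than at T7 in July (two-sided exact permutation p = 0.0476, adjusted over 2 tests 0.0476), and fell by 1.25 log2 from August to September at T7 (two-sided exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). Of the 192, 172 were lower at T7 in September and 14 were called there. Of all 11751 tested probes, 1594 (13.6%) were called there, 847 of them lower, and the median probe fell by 0.15 log2. The 14 calls thus do not set these transcripts apart from other probes. T7 July pool 2 stood at -2.35 and T4 July pool 4 at -3.87, and without these 2 pools the July means were -2.38 and -4.40, a difference of 2.02 log2 that was not tested.

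In July 1 pool of each bed lay closer to the other bed in correlation over all tested probes, T4 pool 4 and T7 pool 2, and an exchange of their labels could account for it. That 1 T4 July pool was closer to T7 is the observation itself and no separate test of this, and neither is the split of the July pools with 148 calls, which exchanges the 2. On the 226 August probes 1 of the 2 scored nearer the other bed, T7 pool 2 at 0.0521, while T4 pool 4 scored 0.242, nearer its own, and T4 pool 3 at -0.0552 also scored nearer T7 (means of the other pools 0.359 at T4 and -0.433 at T7). These scores weaken the case for an exchange, while other values go with it. The latter are no separate evidence, since the 2 pools were picked because they lay closer to the other bed. With the 2 labels exchanged, the July difference between the beds correlated at r = 0.305 with that of August, against 0.286 as labelled. With that of September it was 0.0973 against 0.0389. Both gains are small, and among other splits of the August pools the highest correlation with the July difference as labelled was 0.316. In the set of transcripts above, T7 July pool 2 stood at -2.35, and the other T7 July pools at -4.20 or less. T4 July pool 4 stood at -3.87, and the other T4 July pools at -2.83 or more. An exchange thus cannot be told apart from variation between pools.

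Some probes were well above background in all 5 pools of a group and none of the other. For August between the beds 13 were seen at T4 alone and 1 at T7 alone (highest other split 12), and 35 were seen in August and none in September at T4 (highest other 16). In the remaining comparisons other splits gave as many.

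Of 2655 transcripts with both an S and an AS probe, 879 had both tested, and 278 (10.5%) had both well above background on all arrays. The mean absolute deviation of a pool from its group was 0.441 ± 0.030 log2 (SD, n = 10) in September and 0.484 ± 0.045 (SD, n = 20) in July and August (two-sided permutation p = 0.0125, 100000 resamples). The pools of a group share the mean they are set against, so their deviations are not independent, while the test treats them as if they were. T7 July pool 2 had the highest deviation, 0.587 log2.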
